A study of Homo sapiens with 16 samples.

How the data were processed

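MED1 ChIP-seq was made from 16 HCT116 samples, 8 MED1 libraries and 8 inputs. Reads were aligned with Bowtie 0.12.9 to hg19 and peaks were called with MACS2 2.1.2, per the submitters' processing notes, which name the tools without their settings. Each WT list belongs to both replicates of its condition per the labels, and each MED14-AID list to 1 library. The deposited fold enrichment of a peak is a ratio over background that the authors' caller gave. The deposited −log10 values are those of the peak's q; those of its p are not used here. The deposited score equals 10 times the −log10 q cut to a whole number in every peak of the 6 lists. The lists give no read counts, so the depth of the libraries is unknown and depth could set how many peaks were called. The lowest −log10 q in a list was between 1.58 and 2.76, and weaker binding is not seen here.

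Peaks were compared by overlap of at least 1 bp. Shares have Wilson 95% intervals, which cover the counting of peaks and no difference between cultures. Fisher exact tests are two-sided, the permutation test of peak strength used 100000 resamples, and permutations within 5 or 10 equal parts of a list by −log10 q used 10000. Peaks in a list are not replicates, so these tests compare parts of a list and not conditions. Shifting the peaks 200 times gave chance overlaps with a mean of at most 0.0813% and a maximum of 0.399%. Peaks up to 12.5 kb apart were joined where stitched regions are named. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap counts were tested against bedtools 2.31.1, with 0 of 60 counts different. On simulated data made from the WT DMSO list of 1106 peaks, 300 of 300 copied peaks were recovered and 3 uncopied peaks were called shared. The strength test gave p under 0.05 in 3% of 100 runs with random keeping and in 100% with keeping by strength.

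Named positions followed a rule set before the data were examined, the 8 condition-specific and the 8 shared or kept peaks with the highest authors' fold per comparison, from which those that lead are given. Members of the set of 12 positions outside that rule were chosen after their values were seen. Positions are hg19 and 1-based. The gene table at hand is of GRCh38, and 14 WT DMSO and 13 WT Nutlin-3a peaks lie past its last gene on their chromosome, so no gene was assigned. The planned p53 gene list, p53 motif and promoter comparisons, and the other gene lists, are not analysed here.

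Alternatives planned before the data were examined were a reciprocal overlap of 50%, a gap of 1 kb counted as shared, −log10 q of at least 5 or 10 in both lists, lists of equal length, stitched regions, autosomes and X only, and fold as the measure of strength. A −log10 q of at least 10 in the first list against the complete other list, and leaving out 12 positions, were added after the data were seen. The test of the strongest water peaks in the closing section was first run as a Fisher exact test (p = 0.029 without and 0.27 with Nutlin-3a). It was replaced after that result was seen by an exact McNemar test, because the same peaks are scored in both counts. The rule for reading it was also changed after the results were seen. At first p under 0.05 in a pair of lists counted against a fall by one factor, then both pairs were required, which left it open. Last, the comparison of neighbouring peaks within 10 equal parts by strength, with stitched regions resampled 2000 times, was made the deciding test. Its matching is too coarse to decide, so a fall by one factor is left open.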

Results

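Chromatin occupancy of MED1, a subunit of the Mediator complex that links enhancer-bound transcription factors to RNA polymerase II, was mapped by ChIP-seq in HCT116 cells, a human colorectal carcinoma line. Unmodified (WT) cells received DMSO or Nutlin-3a for 1 h. Nutlin-3a blocks the binding of MDM2 to p53 and thereby induces p53 signalling. In the edited MED14-AID line, the Mediator subunit MED14 carries an auxin-inducible degron, so that auxin together with the plant protein OsTIR1 sends it to the proteasome. These cells received water or 500 µM auxin for 3 h, each without Nutlin-3a or followed by Nutlin-3a for 1 h. Of the 16 samples, 8 were MED1 libraries and 8 were inputs. Each WT condition had 2 MED1 libraries behind 1 joint peak list, and each MED14-AID condition had 1. The 6 lists give peaks and no read totals, so the depth of the libraries is unknown. No difference between conditions could be set against a spread between replicates, and intervals cover the counting of peaks only.

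The WT lists held 1106 MED1 peaks with DMSO and 1254 with Nutlin-3a. The MED14-AID lists held 463 with water and 522 with water and Nutlin-3a. After auxin, 53 peaks were listed without Nutlin-3a and 66 with it. The peaks covered 1145 kb and 1363 kb in WT cells, 466 kb and 520 kb with water, and 38.1 kb and 49.1 kb with auxin. Median peak width lay between 663 bp with auxin alone and 833 bp with water alone. The authors' fold enrichment over background is used here to describe and rank peaks within a list. Its median was 3.19 in WT DMSO and 5.18 with auxin alone.

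**Figure D1:**
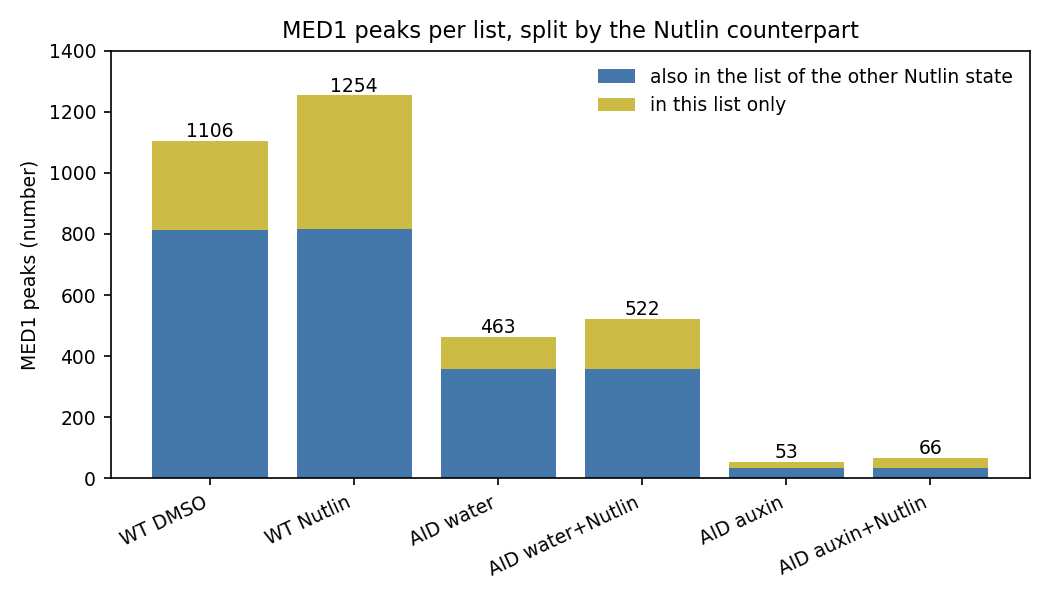
Number of MED1 peaks in each of the 6 lists (vertical axis), with each bar split into peaks that overlap a peak of the list of the same cells in the other Nutlin-3a state (blue) and peaks that do not (yellow). The counts run from 1254 in WT cells with Nutlin-3a to 53 in MED14-AID cells with auxin.

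Merging overlapping peaks gave regions that were compared over all lists. MED1 was listed at 31 regions in all 6 lists. Of the regions present in all 4 lists without auxin, 244 were in neither auxin list, 31 were in both, 12 were in the list with auxin and Nutlin-3a only and 1 was in the list with auxin only. A set of 4 positions stood among the 5 highest folds of every list. These were chromosome 2, 3522238 to 3523390, chromosome 19, 6199154 to 6200117, chromosome 12, 13080166 to 13080975, and chromosome 4, 3747914 to 3748833 (hg19, as listed in WT cells with Nutlin-3a). In that list their folds were 47.5, 36.4, 25.4 and 21.4.

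To see where MED1 appeared after p53 induction in WT cells, the Nutlin-3a list was compared with the DMSO list. MED1 occupied most positions in both conditions, and 439 of 1254 Nutlin-3a peaks (35.0%, Wilson 95% interval 32.4 to 37.7%) overlapped no DMSO peak. In the other direction, 293 of 1106 DMSO peaks (26.5%, 24.0 to 29.2%) overlapped no Nutlin-3a peak. The peaks found only with Nutlin-3a were mostly low, with a median fold of 3.02 against 3.83 for the shared ones. At a fold of at least 5, 15 of 208 Nutlin-3a peaks (7.21%) and 2 of 141 DMSO peaks (1.42%) were absent from the other list. Of those 15, 9 belong to a group of 12 positions, named in the closing section, whose presence did not follow Nutlin-3a across the lists, and without that group 6 of 199 (3.02%) were Nutlin-only. The share of Nutlin-only peaks fell from 35.0% to 15.8% when only Nutlin-3a peaks with −log10 q of at least 10 were compared with the complete DMSO list, a setting added after the data were seen.

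The highest Nutlin-only peak in WT cells lay on chromosome 14, 100743337 to 100745126, with a fold of 13.8. It was also listed in MED14-AID cells with water and Nutlin-3a (fold 3.78) and with auxin and Nutlin-3a (fold 14.6), and in no list without Nutlin-3a. The next lay on chromosome 15, 68131981 to 68133063, with a fold of 12.6. It was listed again with auxin and Nutlin-3a (fold 8.91) and in no other list. The other 6 of the 8 highest were on chromosome 11, from 2016509 and from 116706536, on chromosome 14, from 94844744, 94847221 and 94849000, and on chromosome 19, from 45411361. Their folds in WT cells with Nutlin-3a were between 7.08 and 9.03. All 6 were also listed in MED14-AID cells with water and with auxin in the absence of Nutlin-3a, and none of them with auxin and Nutlin-3a. All 6 are in that group of 12, and whether their signal came from HCT116 chromatin in each library was not tested. Among shared peaks, chromosome 11, 65188356 to 65191266, had the fifth highest fold of the WT Nutlin-3a list (16.3). The highest DMSO-only peaks were on chromosome 1, 32479012 to 32479721 (fold 6.62) and 167189504 to 167190152 (fold 5.31), and neither was in any other list.

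**Figure D2:**
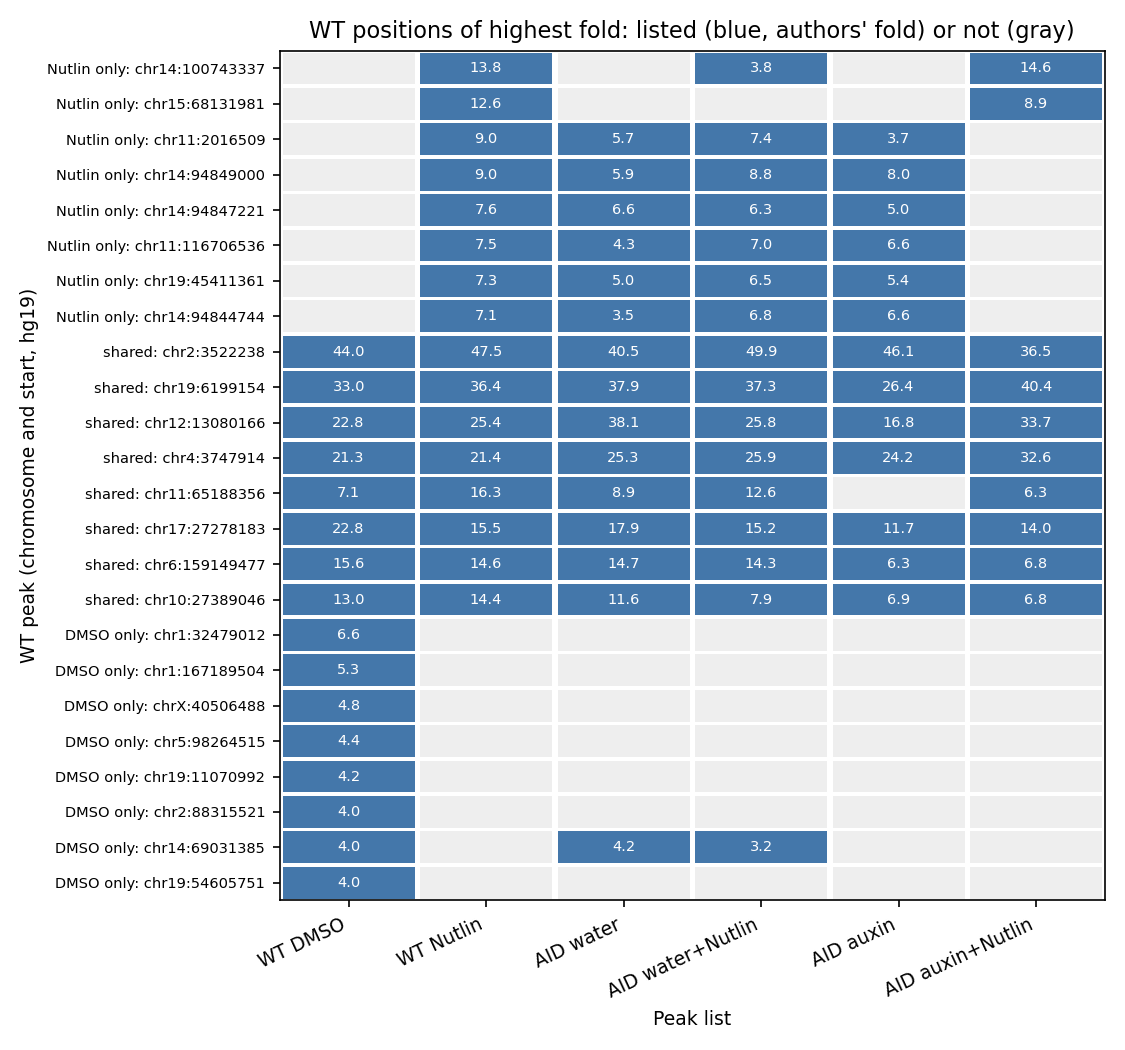
Positions of highest fold in WT cells, by chromosome and start (vertical axis), in the 6 peak lists (horizontal axis). Blue cells carry the authors' fold of the listed peak and gray cells have no listed peak. The chromosome 14 peak from 100743337 is present in the 3 lists with Nutlin-3a only.

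In MED14-AID cells with water, 163 of 522 peaks with Nutlin-3a (31.2%, 27.4 to 35.3%) overlapped no peak of the list without it. Of the peaks without Nutlin-3a, 104 of 463 (22.5%, 18.9 to 26.5%) were absent with it. At a fold of at least 5 the counts were alike, 12 of 167 peaks with Nutlin-3a and 12 of 163 without. The highest Nutlin-only peaks were on chromosome 4, 31086230 to 31087351 (fold 6.22) and 169019401 to 169020020 (fold 6.03), and on chromosome 11, 2152948 to 2153814 (fold 6.03). The pair on chromosome 4 was listed in both WT conditions, and the chromosome 11 position was listed in WT cells with Nutlin-3a and not with DMSO. The highest water-only peaks were on chromosome 1, 24648330 to 24649019 (fold 6.37), and chromosome 21, 35747426 to 35747959 (fold 6.06), and both were listed in both WT conditions. With −log10 q of at least 10 in the Nutlin-3a list and the complete list without it, again added later, 31 of 258 peaks (12.0%) were Nutlin-only.

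Among WT Nutlin-3a peaks also found in MED14-AID cells with water and Nutlin-3a, those Nutlin-only in one line were more often Nutlin-only in the other. Of 416 WT Nutlin-3a peaks that overlapped a peak of MED14-AID cells with water and Nutlin-3a, 25 were Nutlin-only in both lines, 21 in WT cells alone, 75 in MED14-AID cells alone and 295 in neither. The odds ratio was 4.68 (two-sided Fisher exact test, p = 3.6e-06). The test runs over peaks, which are not replicates, and so compares parts of these lists. It leaves out the 838 WT Nutlin-3a peaks that overlapped no peak of MED14-AID cells with water and Nutlin-3a. The mirror comparison of positions listed only without Nutlin-3a gave a similar odds ratio of 4.54 (two-sided Fisher exact test, p = 0.044). The odds ratio is thus not particular to Nutlin-3a.

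After auxin, MED1 peaks were lost at most positions of the water lists. Without Nutlin-3a, 44 of 463 water peaks (9.50%, 7.16 to 12.52%) overlapped an auxin peak, and with Nutlin-3a 47 of 522 (9.004%, 6.84 to 11.8%) did. Leaving out the group of 12 positions, a setting added later, these were 36 of 454 (7.93%) and 47 of 510 (9.22%). The highest kept peaks were those on chromosomes 2, 12, 19 and 4 named above, followed by chromosome 17, 27278229 to 27279146 (fold 17.9 with water alone), and chromosome 20, 1820010 to 1820970 (fold 17.5). The highest lost peak of the water list was on chromosome 20, 30195833 to 30197116 (fold 13.3). It was followed by chromosome 13, 113526964 to 113527834 (fold 12.3), which was listed with auxin and Nutlin-3a (fold 3.66), and chromosome 8, 128258066 to 128260634 (fold 11.03). With Nutlin-3a, the highest lost peaks were on chromosome 18, 3616671 to 3619135 (fold 11.4), chromosome 20, 30194960 to 30197299 (fold 11.3), and chromosome 8, 130721931 to 130723567 (fold 10.0). In the equal-length comparison of the strongest peaks, 21 of 53 water peaks (39.6%) and 31 of 66 with Nutlin-3a (47.0%) were kept. By stitched region the kept shares were 14.7% and 13.98%, and for water peaks with −log10 q of at least 10 against the complete auxin lists, a setting added later, 16.6% and 15.9%. With 50% reciprocal overlap the share with Nutlin-3a was 5.75%.

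**Figure D3:**
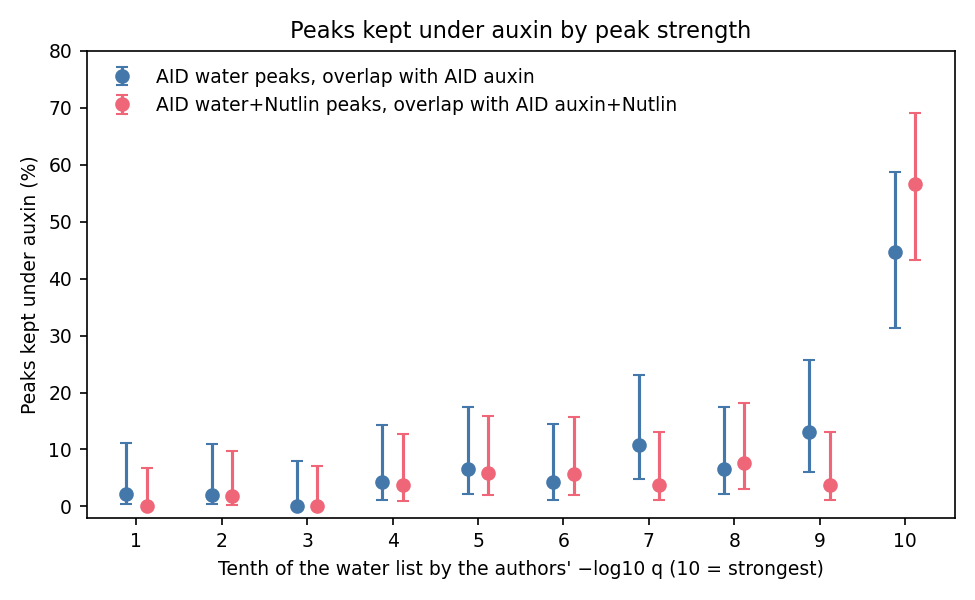
Percent of MED1 peaks of MED14-AID cells with water that overlapped a peak of the auxin list of the same Nutlin-3a state (vertical axis), by 10 equal parts of the water list ordered by the authors' −log10 q (horizontal axis, 10 strongest). Points are shares and bars Wilson 95% intervals. In the strongest part 44.7% were kept without Nutlin-3a and 56.6% with it.

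Kept peaks were stronger than lost ones within the water lists. Their median −log10 q was 25.6 against 8.76 for lost peaks without Nutlin-3a, and 37.0 against 9.19 with it. The probability that a kept peak had the higher −log10 q was 0.805 and 0.857 (area under the ROC curve). Each had a two-sided permutation p = 1e-05, the smallest that 100000 permutations can give. In the strongest of 10 equal parts of each list, 21 of 47 peaks (44.7%, 31.4 to 58.8%) were kept without Nutlin-3a and 30 of 53 (56.6%, 43.3 to 69.0%) with it.

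Under auxin, 32 of 66 peaks with Nutlin-3a (48.5%, 36.8 to 60.3%) overlapped no peak of the list without it, and 20 of 53 peaks without Nutlin-3a (37.7%, 25.9 to 51.2%) were absent with it. Of those 20, 12 are the group of 12 positions, and without it 8 of 41 (19.5%, 10.2 to 34.0%) were absent. The highest Nutlin-only positions were those on chromosome 14, 100743361 to 100745123 (fold 14.6), and chromosome 15, 68132013 to 68133023 (fold 8.91), both Nutlin-only in WT cells too. Chromosome 21, 35747414 to 35748005, followed with a fold of 6.56 and was listed in both WT conditions. The highest peaks lost with Nutlin-3a under auxin were on chromosome 14, 94849057 to 94849850 (fold 7.96), chromosome 4, 74283402 to 74283962 (fold 6.77), and chromosome 11, 116706661 to 116707337 (fold 6.63). These 3 were Nutlin-only in WT cells and are in the group of 12. Of the peaks listed under auxin, 9 of 53 without Nutlin-3a and 17 of 66 with it overlapped no peak of the matching water list.

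**Figure D4:**
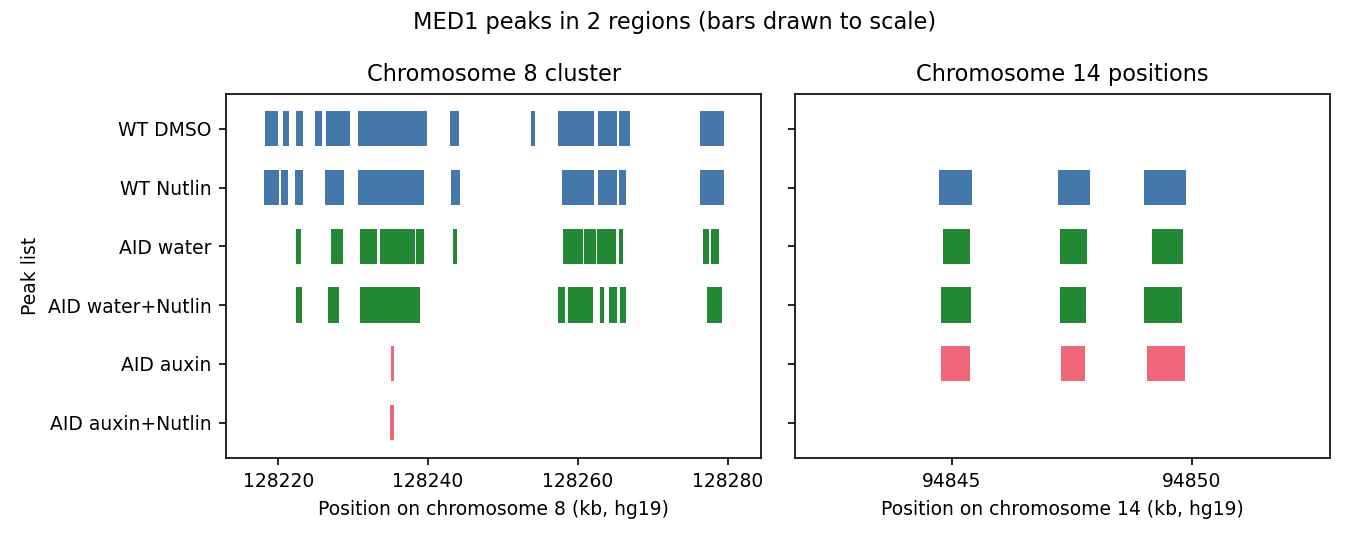
MED1 peaks of the 6 lists (vertical axis) along part of chromosome 8 and part of chromosome 14 (horizontal axes, kb, hg19), with each bar 1 peak, blue for WT cells, green for MED14-AID cells with water and red with auxin. The chromosome 8 cluster has 1 peak in each auxin list, and the chromosome 14 positions are absent from WT DMSO and from auxin with Nutlin-3a.

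Of the WT DMSO peaks, 368 of 1106 (33.3%, 30.6 to 36.1%) overlapped a peak of MED14-AID cells with water, and with Nutlin-3a 416 of 1254 (33.2%, 30.6 to 35.8%) did. In reverse, 394 of 463 water peaks (85.1%, 81.6 to 88.1%) were in the WT DMSO list and 453 of 522 (86.8%, 83.6 to 89.4%) in the WT Nutlin-3a list. The line differed together with the mock treatment, the number of libraries and the date of deposit. MED14-AID samples without Nutlin-3a were given no DMSO hour per the labels, unlike the WT samples. Taking as many of the strongest WT peaks as the MED14-AID list held, 270 of 463 (58.3%) and 319 of 522 (61.1%) were shared. For WT peaks with −log10 q of at least 10 against the complete MED14-AID lists, added later, the shares were 55.4% and 50.9%.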

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

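All tests in this part were chosen after the results they address were seen. A group of 12 positions was listed in WT cells with Nutlin-3a and not with DMSO, and in MED14-AID cells with auxin and not with auxin and Nutlin-3a. Nutlin-3a thus went with opposite changes in WT cells and under auxin, and that difference was not tested. The positions fall into 10 stitched regions. They lie on chromosome 1 from 142536234 and 161192113, chromosome 4 from 74283402 and 155490246, chromosome 11 from 2016509, 116691643 and 116706536, chromosome 14 from 94844744, 94847221 and 94848999, chromosome 16 from 72093906 and chromosome 19 from 45411361. In WT cells with Nutlin-3a, 11 of them had folds of 3.70 to 9.03, and the chromosome 1 position from 142536234 had 1.58. They include 9 of the 15 Nutlin-only WT peaks at a fold of at least 5.

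The group was chosen for being listed with auxin alone and not with auxin and Nutlin-3a. That choice already goes against Nutlin-3a treatment as the whole cause of these 12 positions, so it was not tested. In MED14-AID cells, 8 of them were listed with water alone and 11 with water and Nutlin-3a. Of all auxin peaks, 44 of 53 overlapped a water peak, so the 8 add no separate support. Weak peaks missed near the threshold in WT DMSO stay open for the group. The rule against them asked every position to reach the median −log10 q of the WT Nutlin-3a list, 11.4. Of the 12, 11 did, and the position from 142536234, at 5.25, did not. The median of the group was 42.4, against 7.34 for the other Nutlin-only WT peaks. The group was also chosen for being in the short auxin list, where kept peaks were the stronger ones, so that contrast adds no separate support. Absence from WT DMSO defined the group, so the absence itself was not tested. An exchange of labels between the 2 auxin lists cannot be told apart from correct labels. Of the regions in the auxin list only, 2 were in the water list alone and 6 in the list with water and Nutlin-3a alone. For those only in the auxin list with Nutlin-3a, the counts were 7 and 2 (two-sided Fisher exact test, p = 0.057). Among the 6 are 3 positions of the group to be explained, so the test is not independent of it. The chromosome 14 and 15 positions that lead the Nutlin-only WT peaks were in the auxin list labelled with Nutlin-3a. The chromosome 15 position was not listed with water and Nutlin-3a. The group itself, with 9 of the 15 Nutlin-only WT peaks at a fold of at least 5, was in the auxin list labelled without Nutlin-3a. These positions go both ways and do not decide on the labels. DNA from another source in some of the libraries stays open and untested, as the positions of the group were not assigned to genes here.

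Peaks with a neighbouring peak within the stitching distance made up 31.8% of the peaks kept under auxin and 58.5% of those lost without Nutlin-3a (two-sided Fisher exact test, p = 0.0012), and 38.3% and 59.2% with it (p = 0.0081). Within 10 equal parts by −log10 q, differences of −25.1 and −23.6 percentage points were left (permutation p = 0.0009 and 0.0001). The latter p is the smallest that 10000 permutations can give. These tests and the Fisher tests treat peaks of a cluster as independent, which they are not. With whole stitched regions resampled, the differences were −24.9 (95% interval −38.6 to −9.82) and −23.6 points (−34.8 to −11.0). Every interval stayed under 0 when matched by fold or without the group of 12. Strength was not matched further within a part. The strongest part held 21 of the 44 peaks kept without Nutlin-3a and 30 of the 47 with it. Lower strength of such peaks therefore stays open as the whole cause. So does a fall of all peaks by one factor, with only the strongest left over the threshold. Of the 44 strongest water peaks, 21 were kept and 32 were among the 44 strongest of the other water list (exact McNemar test, p = 0.0074). With Nutlin-3a these were 29 and 35 of 47 (exact McNemar test, p = 0.18). Neither count decides on a fall by one factor, since overlap with a short auxin list is set against rank in a longer water list. By stitched region, 14.7% with 1 water peak and 13.6% with 2 or more had a kept peak, and 13.0% and 16.04% with Nutlin-3a, and what sets the difference between single and neighbouring peaks stays open.

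The Nutlin-only positions shared by WT and MED14-AID cells were weighed against weak peaks missed near the threshold in both lines. An odds ratio of 3.67 was left within 5 equal parts by −log10 q in the WT Nutlin-3a list (permutation p = 0.0002), against 4.68 without strata. Strength in the MED14-AID lists was not matched, so misses in both lines stay open. Nutlin-3a treatment alone cannot be told apart from other causes. The mirror comparison of positions listed only without Nutlin-3a gave an odds ratio of 4.54 (two-sided Fisher exact test, p = 0.044), from 4 positions in both lines, 4 in WT alone, 65 in MED14-AID alone and 295 in neither.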

How the results depend on the processing

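The settings called added were chosen after the data were seen. Of the percentages under the settings chosen beforehand, 31 stayed within their 95% intervals and 18 did not. The odds ratio of shared Nutlin-only positions (3.88 to 6.27 over 7 settings chosen beforehand, 6.66 in the added one) and the strength of kept peaks (0.794 to 0.860 over the 7 settings run for each list, without equal lengths, stitched regions or the added limit) kept direction and side of 0.05. Nutlin-only shares in WT were 43.1% with 50% reciprocal overlap, 31.2% with a 1 kb gap, 37.7% at −log10 q of at least 10 in both lists, 30.7% with equal lengths and 15.8% with the added limit on the first list. In MED14-AID cells with water they were 43.3%, 36.0% at −log10 q of at least 10 and 12.0% with the added limit. Kept shares under auxin were 13.4% at −log10 q of at least 10, 39.6% with equal lengths, 14.7% by stitched region and 16.6% with the added limit. With Nutlin-3a they were 5.75% with reciprocal overlap, 47.0% with equal lengths, 13.98% by stitched region and 15.9% with the added limit. WT peaks in MED14-AID were 24.8%, 36.3%, 58.3% and 55.4% with reciprocal overlap, the gap, equal lengths and the added limit, and 24.0%, 37.0%, 61.1% and 50.9% with Nutlin-3a. Equal lengths compare fewer and stronger peaks by construction, and the cause of the other shifts was not tested. Gene assignment, motif and promoter alternatives were not run. No paired analysis was possible because each WT condition has 1 joint list and each MED14-AID condition 1 library. Unknown depth limits every count of absent peaks, since a peak under the authors' threshold is not listed.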

Other observations

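All comparisons in this part were chosen after the lists were seen. MED1 peaks in the lists without auxin often stood in clusters. With neighbouring peaks joined into stitched regions, the cluster with the most peaks over all lists together spanned chromosome 4, 30754482 to 30842360. It had 18 and 19 peaks in WT cells with DMSO and Nutlin-3a, 11 and 9 with water, and 1 in each auxin list. Chromosome 6, 159118377 to 159160165, had 10, 13, 10 and 10 peaks in the lists without auxin, and chromosome 8, 128218068 to 128279465, had 12, 10, 12 and 9, with 1 in each auxin list at both. Chromosome 18, 3594059 to 3627439, had 7, 7, 7 and 6 and none in the auxin lists. Of 46 joined regions with at least 3 water peaks, 35 had no peak in either auxin list. The 46 regions held 190 water peaks, 10 auxin peaks and 10 with auxin and Nutlin-3a.

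Of 20 regions in the auxin list and not in the list with auxin and Nutlin-3a, 14 were absent from WT DMSO, against 4 of 30 the other way round. The group of 12 positions, chosen for that absence, makes up 12 of the 14, so no test is given. Among regions Nutlin-only in both lines, 3 were in the auxin list alone and 2 in the auxin list with Nutlin-3a alone. Those 3 belong to the group of 12, which was chosen for that pattern.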
